A study of Mus musculus with 8 samples.

How the data were processed

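Genomic DNA of 8 mouse cell lines was enriched by hybrid capture (Agilent SureSelect XT, Mouse Methyl-Seq kit) for bisulfite sequencing, per the labels' protocols. The lines were grouped from the labels into 4 IDH mutant tumour lines, 2 IDH wild-type tumour lines and 2 IDH wild-type astrocyte lines. Reads were aligned to mm10 with Novoalign 3.7.1 and handled with Picard, per the submitters' processing notes; the step that called the regions, the methylation caller and any filter are not given in the sources used here.

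The file analysed was 1 list of regions for the whole series. The track line declares the narrowPeak type, and its name carries the words min10 and targets, per the file headers. Each region has a start, an end and a score, a whole number of at least 100 that was deposited by the authors as 1 value for the whole series. No column holds a methylation level or a value of a single line. All coordinates lie on a grid of 10 bp, no region is narrower than 100 bp, and neighbouring regions are at least 60 bp apart. The last digits 4 and 9 never occur among the 220894 scores. The digits that do occur are those that 10 times a mean of 8 whole numbers, cut to a whole number, can end in. With the multiplier of 10 held fixed, of the divisors from 1 to 24 only 8, the number of lines, gives this set. Other multipliers were not tried, so the digits alone do not show that 8 whole numbers were averaged. What those whole numbers count is not given in the sources used here. The score was used only to describe, rank and filter regions within this list. With no counts per line, the depth of each line is unknown, and no interval, replicate spread or test between groups could be given.

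The comparisons of IDH mutant with wild-type lines and of tumour with astrocyte lines, and the overall methylation level per line, had been planned for values per line and were not run. The planned test of promoters became a test of gene ends, because the gene table used gives the start and end of each gene but no strand and no exons. That table is on the RefSeq assembly GRCm38.p6, the assembly that mm10 names, and held 21883 protein-coding genes on chromosomes 1 to 19, X and Y. Coordinates are printed counting from 1.

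A region was placed at a gene end if it shared at least 1 bp with the 1000 bp to each side of the start or end of a protein-coding gene, otherwise in a gene body, otherwise between genes. The shares were compared with 1000 shuffles that kept each region's width and chromosome and placed it at random between the first and last region of that chromosome (100 shuffles for each alternative). Shuffled regions were free to overlap. Shares of regions carry 95% Wilson intervals and shares of genes exact (Clopper-Pearson) intervals, which cover counting error only. Of 348 genes on 17 lists fixed before the data were examined, 347 matched a gene symbol and 1 matched a synonym; 343 were protein-coding and were tested. H19, Kcnq1ot1, Meg3, Airn and Peg13 are listed as non-coding and were left out. The lists were human glioma CIMP and IDH-linked genes, DNA methylation and chromatin machinery, tumour suppressors, receptor tyrosine kinase, RAS and PI3K genes, Wnt antagonists, developmental transcription factors, Hox genes, markers of astrocytes, oligodendrocytes, neurons, microglia and immune cells, endothelial and mural cells and mesenchymal cells, stem and progenitor genes, germline, imprinted and housekeeping genes. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment. The background planned for a list with scores was the set of genes with a region at an end. Every gene in that set has a region, so the test of any region needs all protein-coding genes as background, and the planned background was used only with the upper 25% of regions by score. Genes the kit does not target remain in the background, since its target list was not used here.

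The named genes follow a rule fixed before the data were examined: the 15 genes with the highest scoring region at an end, leaving out predicted genes and genes named only by a RIKEN clone (symbols with Gm or Rik, and those with LOC, which were added to the rule later) and counting a shared region once; up to 4 members of each list with the highest scores; and a set of single genes, of which Idh1, Atrx, Cdkn2a, Mgmt and Pdgfra are given. Some genes that the rule or the lists name are not reported here. List members without a region are named as exceptions after their values were seen. For those single genes, the median score over regions in the gene and 1000 bp to each side was ranked among protein-coding genes whose number of regions differed by at most 2, with at least 3 regions. Because wider regions had higher scores, medians over regions of 400 to 800 bp, and the percentile of each region's score among all regions within 50 bp of its width, were added after the data were examined. Alternatives were windows of 500 and 2000 bp, the region midpoint in place of 1 bp of overlap, the upper 25% of regions by score, all annotated genes, autosomes only and merged regions; others were added after seeing the data.

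The tests were tested on simulated data. Of 20 sets of regions placed at random, 2 gave p under 0.05 in the position test, and putting 10% of 20000 simulated regions on gene ends raised the share by 9.77 percentage points. Of 200 random lists of 20 genes, 8 had an unadjusted p under 0.05 and 0 an adjusted one, by Fisher's exact test. All 50 lists of 20 covered genes passed. These lists held only genes with a region, so that outcome was fixed in advance and tells nothing about partly covered lists. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.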

Results

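The series profiled DNA methylation by bisulfite sequencing in 8 mouse cell lines, after enrichment of genomic DNA with a capture kit made for mouse methylation sequencing. The lines fell into 4 brain tumour lines with mutant IDH, 2 brain tumour lines with wild-type IDH described as RAS gliomas, and 2 immortalized astrocyte lines with wild-type IDH. IDH1 encodes the cytosolic isocitrate dehydrogenase, and the mutant form found in human glioma makes 2-hydroxyglutarate, which inhibits the enzymes that remove DNA methylation. The mutant tumour lines and the astrocyte lines came from mice with a genotype that included floxed Cdkn2a and Atrx, whereas the wild-type tumour lines came from mice with floxed Cdkn2a alone. Mutant and wild-type tumour lines thus also differed in the genotype of the mice, Atrx included, and mutant tumour lines and astrocyte lines also differed in cell type. Exogenous wild-type IDH1 was expressed in 1 of the astrocyte lines. Both astrocyte lines carry PDGFA in their line names, and the mutant tumour lines do not. The study set IDH mutant against wild-type lines, to ask where their DNA methylation differs. The values analysed here were 1 list of covered genomic regions for the whole series, each with a position and a score given by the authors and with no value for any single line. Methylation levels and the comparison of mutant with wild-type lines were therefore not analysed here, the depth of each line is unknown, and no value below has a replicate error. What follows describes which genes, gene groups and chromosome segments the pooled list covered.

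The list reached all 21 chromosomes, and was densest on chromosome 11 and sparsest on Y. It held 220894 regions that did not overlap each other and together spanned 119 Mb, or 4.46% of the sequence between the first and the last region of each chromosome. The median width was 460 bp, with quartiles of 260 and 680 bp, and the widest region measured 16470 bp. The median score was 462, with quartiles of 235 and 768 and a lowest value of 100. Scores of 1000 or more belonged to 29518 regions (13.4%), and scores under 200 to 43575 regions (19.7%). On the autosomes the density ran from 67.2 regions per Mb on chromosome 3 to 132 per Mb on chromosome 11. Chromosome X held 36.6 regions per Mb with a median score of 402, against a median of 463 over the autosomes. Score rose with width (Spearman rho = 0.803 across regions, which are not independent replicates), and among regions of 400 to 800 bp the median was 658 on X and 635 on the autosomes. Chromosome Y held 87 regions, with a median width of 230 bp and a median score of 192. The 15 of them with a width of 400 to 800 bp had a median score of 551.

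Regions were concentrated at the ends of protein-coding genes. Within 1000 bp of either end of a protein-coding gene lay 33601 regions, or 15.2% (95% Wilson interval 15.1 to 15.4), 3.85 times the 3.95% ± 0.042 (SD over 1000 shuffles) reached when the regions were placed at random on their own chromosomes. A further 94336 regions (42.7%) lay inside gene bodies, against 38.8% of shuffled regions, and 92957 (42.1%) lay between genes, against 57.3%. Each of these shares lay outside the range of all 1000 shuffles, with a two-sided permutation p of 0.002, the smallest that 1000 shuffles can give. Regions at gene ends were wider, with a median of 570 bp against 420 bp between genes, and had a median score of 502 against 440. Among regions of 400 to 800 bp the order was the opposite, with medians of 545 at gene ends, 635 in gene bodies and 666 between genes. Of 21883 protein-coding genes, 16744 (76.5%) had a region at an end, 6456 (29.5%) had regions at both ends, and 5139 (23.5%) had none at either. Over the genes with a region at an end, the highest score at an end had a median of 783. The end scores of list members named below can be set against that value, and are not matched for width. Strand was not given in the gene table, so the end that carries the promoter could not be separated from the other end. The target list of the capture kit was not used here, so these shares describe captured and sequenced DNA together and cannot be set against the sequence the kit targets.

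Homeobox and other developmental transcription factor genes were covered more often than other genes. All 39 Hox genes measured, which set position along the body axis, had a region at an end, compared with 76.5% of the other protein-coding genes (adjusted exact p = 0.00033), and 29 of them had regions at both ends. Of 73 developmental transcription factor genes outside the Hox clusters, 70 (95.9%, exact 95% interval 88.5 to 99.1) had a region at an end (adjusted exact p = 0.00018), and 44 had regions at both. Gata4 and Alx4 were among the 3 exceptions. The highest scores among Hox gene ends were 1872 at Hoxb8 (chromosome 11, 96278551 to 96279380), 1822 at Hoxa7 (chromosome 6, 52217141 to 52219940), 1803 at Hoxb7 and 1727 at Hoxa3. Outside the clusters they were 1621 at Gata3, a regulator of T cell and other lineages (chromosome 2, 9886891 to 9887560), 1553 at Lhx2, a forebrain patterning factor, 1437 at Foxf1 and 1336 at Msx1. All adjusted exact p values come from a two-sided Fisher's exact test of list members against all other protein-coding genes, with Benjamini-Hochberg adjustment over 17 lists. Genes that the capture kit does not target remained among the other genes, so these tests cannot separate the choice of targets from the lines. With olfactory, vomeronasal and predicted genes taken out of the background, 84.5% of other genes had a region at an end. The Hox and developmental lists still passed, with a larger p (adjusted exact p = 0.028 for each). Neighbouring Hox genes can share a region, so they are not independent, and neither list passed when only the upper 25% of regions by score was counted (61.5% of Hox genes, adjusted exact p = 0.066, and 38.4% of the other factors, adjusted exact p = 1.0). The background planned for a list with scores, genes with a region at an end, gave the same outcome for the upper 25% (61.5% of Hox genes, adjusted exact p = 0.44, and 40% of the other factors, adjusted exact p = 0.24).

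Tumour suppressor and neuronal genes were also covered more often. All 18 tumour suppressor genes had a region at an end (exact 95% interval 81.5 to 100, adjusted exact p = 0.048), with high scores at Trp53 (1347), Nf1, a negative regulator of RAS (1308), and Dapk1 (1300). All 20 neuronal marker genes had one too (exact 95% interval 83.2 to 100, adjusted exact p = 0.040), with the highest scores at Eomes (1338), Tubb3 (1076), Snap25 (1066) and Neurod2 (947). With olfactory, vomeronasal and predicted genes taken out of the background, 84.6% of other genes had a region at an end and neither list passed (adjusted exact p = 0.32 for tumour suppressors and 0.26 for neuronal genes), and neither passed with windows of 2000 bp (adjusted exact p = 0.15 and 0.12), with regions required at both ends (0.20 and 0.35) or with the upper 25% by score (0.30 and 0.77). The neuronal list also did not pass with windows of 500 bp (80.0%, adjusted exact p = 0.75) or with region midpoints (95%, adjusted exact p = 0.092).

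The remaining 13 lists did not pass the test. All 15 housekeeping genes and all 15 stem and progenitor genes had a region at an end (adjusted exact p = 0.084 for each), and both lists passed with windows of 500 bp (adjusted exact p = 0.031 for each). Among them Polr2a, the largest subunit of RNA polymerase II, scored 2235, Ywhaz 1312, Actb 1233 and Ppia 1162, and the pluripotency-linked genes Klf4 and Nanog scored 1808 and 1080, with Bmi1 at 1292 and the telomerase gene Tert at 1245. All 14 genes of the list taken from human glioma with the CpG island methylator phenotype or IDH mutation were covered (exact 95% interval 76.8 to 100, adjusted exact p = 0.12). Its highest scores were 1080 at Ldha, which encodes lactate dehydrogenase A (chromosome 7, 46841421 to 46842080), 1040 at Rhof, 857 at Lgals3 and 791 at Sowaha. All 9 Wnt antagonist genes were covered (adjusted exact p = 0.24), with Sfrp4 at 948, Sox17 at 923, Sfrp1 at 698 and Dkk3 at 658. Of 20 receptor tyrosine kinase, RAS and PI3K genes, 18 were covered (adjusted exact p = 0.33), with Pdgfra at 1478, Egfr at 1440 and Spry2 at 1040; Pdgfb was among the 2 that were not. Of 18 genes of the DNA methylation and chromatin machinery, 14 were covered (77.8%, adjusted exact p = 1.0), including Tet3 (1247), Daxx (1220), Tet1 (1181) and Suz12 (1171). The ends of Dnmt1, Dnmt3a, Idh2 and Kdm4c lacked a region, although Dnmt1, the maintenance methyltransferase, had 7 regions and Idh2 had 5 in or near the gene.

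Coverage of astrocyte, oligodendrocyte, mesenchymal and endothelial marker genes did not pass the test against other genes, and microglia and immune markers had the lowest share of the 17 lists with windows of 1000 bp. Of 16 astrocyte markers, 14 (87.5%) had a region at an end (adjusted exact p = 0.51), with 2076 at the glial glutamate transporter gene Slc1a2 (chromosome 2, 102656971 to 102657430), 1593 at Aldoc, 1195 at Slc4a4 and 1035 at Glul; Aqp4 and Nfia had none. Of 16 oligodendrocyte lineage markers, 14 were covered (adjusted exact p = 0.51), with Mag at 947, Olig1 at 892 and Cnp at 866 after Pdgfra. Of 14 mesenchymal and fibroblast markers, 11 were covered (adjusted exact p = 1.0), with Acta2 at 1616, Snai2 at 1283, Vim at 1123 and Snai1 at 508. Of 11 endothelial and mural markers, 8 were covered (adjusted exact p = 0.88), with Cdh5 at 728, Kcnj8 at 615, Cldn5 at 536 and Erg at 531. Of 15 microglia and immune markers, 8 (53.3%, exact 95% interval 26.6 to 78.7) were covered (adjusted exact p = 0.13), with Ptprc at 1127, Cd68 at 911, Cx3cr1 at 768 and C1qa at 620; Aif1, Cd3e, Csf1r, Itgam, P2ry12 and Trem2 were among the 7 that had none. With olfactory, vomeronasal and predicted genes left out of the background, this list was lower than the 84.6% of other genes (adjusted exact p = 0.028), whereas with windows of 2000 bp it was at 80.0% against 81.0% of other genes (adjusted exact p = 1.0) and the endothelial list was lower, at 72.7%. With both ends required the germline list was the lowest (6.25%), and with the upper 25% by score the endothelial list (0 of 11 genes, adjusted exact p = 0.066). Of 16 germline genes, 13 were covered (adjusted exact p = 1.0), with Tex12 at 1200, Hormad1 at 997, Slc25a31 at 850 and Dazl at 646. Of 15 imprinted protein-coding genes, 14 were covered (adjusted exact p = 0.34), with Grb10 at 1377, Impact at 987, Plagl1 at 962 and Nnat at 892; Snrpn was the exception.

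**Figure D1:**
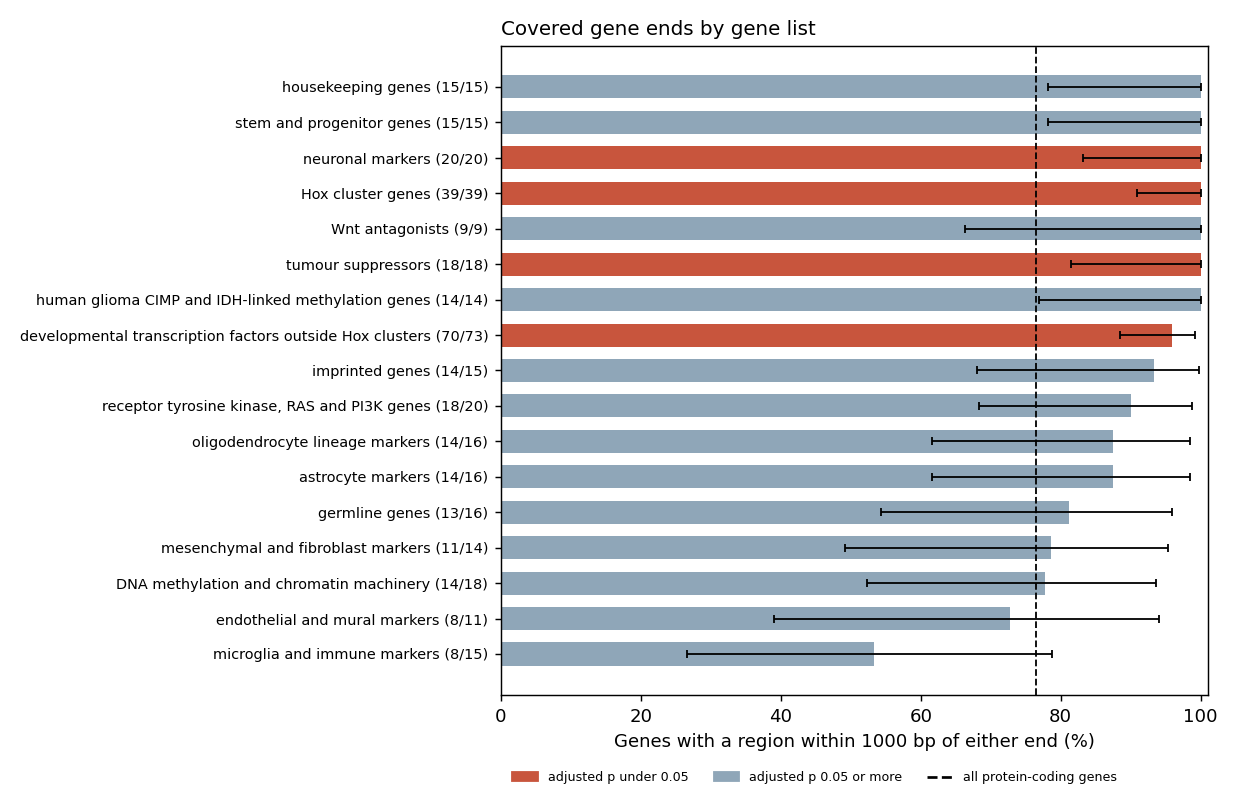
Percentage of genes in each of 17 lists with a region within 1000 bp of either gene end (horizontal axis), with exact 95% binomial intervals and the number of covered over measured genes beside each list. The dashed line marks the 76.5% of all protein-coding genes; the 4 red bars (neuronal markers, Hox cluster genes, tumour suppressors and developmental transcription factors) passed an adjusted p under 0.05, and the microglia and immune bar is the lowest at 53.3%.

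Among the single genes given here, the median pooled score, not matched for width, was highest for Idh1 and lowest for Cdkn2a. Of these genes, Idh1, Atrx and Cdkn2a belong to the genotypes of the lines or mice described above. Idh1 (chromosome 1, 65158616 to 65186479, mm10) had 7 regions with a median score of 860, above 92.5% of the 5869 protein-coding genes with a similar number of regions. Its highest score, 1715, lay inside the gene at 65176821 to 65179100. Atrx, a chromatin remodeller on chromosome X (105797615 to 105929372), had 13 regions with a median of 290, above 11.1% of 1582 comparable genes, and its highest score, 1118, lay at the higher-numbered end. Cdkn2a, which encodes the cell cycle inhibitors INK4A and ARF (chromosome 4, 89274473 to 89294619), had 5 regions with a median of 156, above 0.899% of 8678 comparable genes. The highest of these, 623, lay at 89281191 to 89282330, and the 6718 bp of the gene below it held no region. Mgmt, a DNA repair gene whose methylation is measured in human glioma, had 15 regions with a median of 552, and Pdgfra, a growth factor receptor gene, had 15 with a median of 322. Set against all regions within 50 bp of the same width, the scores had a median percentile of 68.2 at Idh1, 62.7 at Atrx, 23.2 at Cdkn2a, 40.9 at Mgmt and 41.4 at Pdgfra. These are percentiles of single regions among regions, so they are not ranks among genes. The Atrx regions were narrow, with a median width of 270 bp, and as a median their scores were not low for that width. Ranks among genes at matched width were not computed, so how far region width accounts for the ranks is unknown. Each median is taken over the 8 lines together, and the contribution of each line to it is not known.

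**Figure D2:**
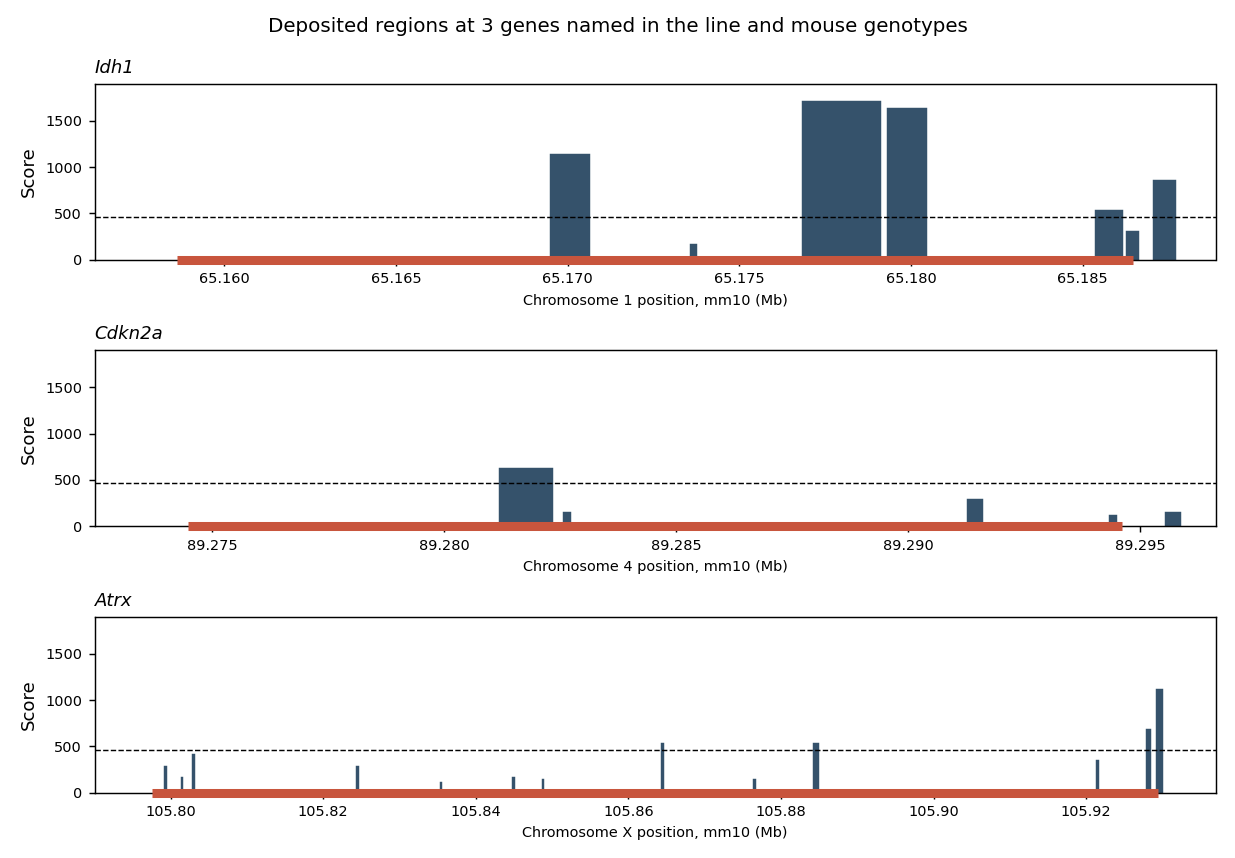
Deposited regions at Idh1, Cdkn2a and Atrx, drawn to scale along each chromosome (horizontal axis, Mb in mm10) with the score of each region as bar height; the red line is the gene and the dashed line the median score of all regions, 462. The bars at Cdkn2a stay at 293 or below apart from 1 region at 623, whereas Idh1 reaches 1715.

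With predicted genes and genes named only by a RIKEN clone left out, 8 of the 15 genes with the highest scoring end regions lay in a zinc finger gene cluster of chromosome 4, with their regions between 145509921 and 147555710. These were Zfp990 (19053), Rex2 (16517), Zfp991 (15326), Zfp980 (14257), Zfp600 (13093), Zfp985 (12901), Zfp988 (11947) and Zfp981 (11541). The others were Sfi1 (37878), Duxf3 (32545), Lars2 (28288), Pisd (22958), Slc30a4 (10502), Zfp996 (7775) and Dgkh (7481). Whether reads at these genes also match other copies in the genome was not tested here, so the scores of members of gene families, the Zfp genes among them, are uncertain.

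Scores varied along the chromosomes, and the distal part of chromosome 4 had the lowest run. Among regions of 400 to 800 bp, the median score was 488 on chromosome 4 beyond 120 Mb and 640 on the rest of the autosomes, a ratio of 0.763 (95% bootstrap interval 0.743 to 0.785). The ratio was 0.755 (0.732 to 0.793) for regions more than 10000 bp from any protein-coding gene end and 0.781 (0.756 to 0.815) for regions nearer to one. Among whole autosomes the median score of all regions, not matched for width, ran from 407 on chromosome 4 to 521 on chromosome 13. Among regions of 400 to 800 bp it ran from 571 on chromosome 4 to 715 on chromosome 10. Across 497 autosomal segments of 5 Mb, the log2 median score was lower where there were more protein-coding genes (Pearson r = -0.54 with the log2 gene number, across segments, which are not independent replicates). These intervals cover sampling of regions only, and neither the segment boundary nor the width range was fixed before the data were examined.

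**Figure D3:**
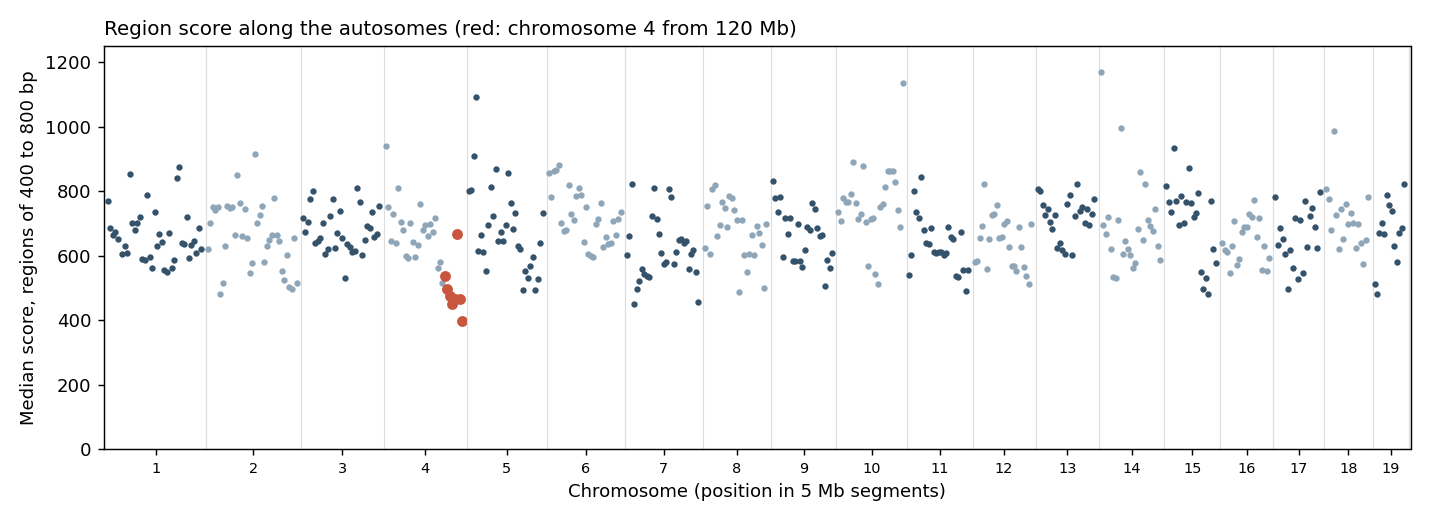
Median score of regions of 400 to 800 bp (vertical axis) in each 5 Mb segment along the 19 autosomes (horizontal axis), with 1 point per segment. The 8 red points are chromosome 4 beyond 120 Mb; 7 of them lie at 537 or below, and the other, at 145 to 150 Mb, lies at 667.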

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

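The share of regions at gene ends kept its direction and its side of the threshold under the 6 alternatives run, from 10.8% with windows of 500 bp to 23.2% with all annotated genes. Alternatives chosen after seeing the data were the smaller background, both ends required, the upper 25% by score among covered genes (a background named before, in a combination set after), genes without a window and the list without scores of 10000 or more. The upper 25% of regions by score numbered 55313, with a median width of 720 bp. By Fisher's exact test 4 lists passed, 6 at an unadjusted p under 0.05. With windows of 2000 bp 2 passed, and with regions at both ends 2, each time the Hox and developmental lists. With the upper 25% by score 0 passed, and 0 again among covered genes only. With windows of 500 bp 5 passed and with region midpoints 3. With olfactory, vomeronasal and predicted genes out of the background 3 passed, of which 2 had passed before; the third was the microglia and immune list, which was lower. Among the lists that changed sides relative to other genes, the developmental and neuronal lists had passed in the main setting. The astrocyte list was at 62.5% both with windows of 500 bp and with region midpoints, and the mesenchymal list at 78.6% with windows of 2000 bp. With both ends required, the astrocyte, germline and imprinted lists were at 25%, 6.25% and 20%. With the smaller background, the chromatin, mesenchymal and germline lists kept 77.8%, 78.6% and 81.2%, now under the 84.6% of other genes by construction of that background. With the upper 25% by score, the glioma CIMP, Wnt antagonist, developmental, astrocyte, oligodendrocyte, neuronal, mesenchymal and germline lists were at 28.6%, 22.2%, 38.4%, 37.5%, 37.5%, 30%, 21.4% and 18.8%, against 39.5% of other genes. Among covered genes only, the glioma CIMP, kinase, Wnt antagonist, developmental, astrocyte, oligodendrocyte, neuronal, mesenchymal, germline and imprinted lists were at 28.6%, 44.4%, 22.2%, 40%, 42.9%, 42.9%, 30%, 27.3%, 23.1% and 42.9%, against 51.6%. Apart from the smaller background, the cause was not tested. Of 258 region counts for 86 named genes under other windows, 245 were within 1.5 times the main count. Settings that need values per line (coverage minimum, adjusted p, logit scale, minimum difference, leaving out each line, and the mean methylation over autosomes) were not run, since the list has no such values. No paired analysis was possible because the list carries no value of any line. The depth of each line is unknown, so a gene without a region is one that did not reach the list, not one without reads.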

Other observations

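Coverage of gene ends differed widely between gene families. Families were picked by symbol after the data were seen and compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted over 14 families. Of 1110 olfactory receptor genes, 161 (14.5%, exact 95% interval 12.5 to 16.7) had a region at an end, and of 355 vomeronasal receptor genes, which detect pheromones, 19 (5.35%, adjusted exact p = 5.8e-186). Keratin-associated protein genes were at 10.7% (6 of 56, adjusted exact p = 9.2e-25) and beta-defensin genes, which encode antimicrobial peptides, at 16.7% (7 of 42, adjusted exact p = 1.4e-15). Cytochrome P450 genes (57.6%, adjusted exact p = 6.6e-05) and genes of interleukins and their receptors (61.4%, adjusted exact p = 0.0035) were also below other genes. Clustered protocadherin genes, which encode neuronal adhesion proteins, were covered in 56 of 57 cases (adjusted exact p = 1.2e-05) and ribosomal protein genes in 94 of 97 (adjusted exact p = 1.1e-07). Fox genes were covered in 43 of 44 (adjusted exact p = 0.00035), Sox genes in 19 of 19 (adjusted exact p = 0.015) and Zfp genes in 365 of 397 (adjusted exact p = 1.7e-15). Collagen, cadherin and Wnt ligand genes did not pass (adjusted exact p = 0.12, 0.81 and 0.072). Many of these genes lie in arrays, and neighbours are not independent. The target list of the capture kit was not used here, so these shares can reflect which genes the kit targets. The p values therefore do not show a property of the lines.

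Regions filled much of the Hox clusters. They covered 53.5% of the Hoxa cluster (chromosome 6, 52155367 to 52260880), 36.2% of Hoxb, 29.8% of Hoxc and 36.4% of Hoxd. Other windows of the same length on the same chromosomes had medians of 2.88%, 6.36%, 2.77% and 3.40%, and 1 of 681 was as high for Hoxb and 0 for the others. The protocadherin clusters on chromosome 18 were covered over 15.1% of 912 kb, with 0 of 94 other windows as high. Among short RNA genes, 60.0% of tRNA genes and 50.9% of snoRNA genes overlapped a region, against 16.3% of miRNA and 9.26% of snRNA genes. A region can overlap several such genes, so they are not independent. Whether reads there also match other copies in the genome was not tested.

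Of the tests below, those on Cdkn2a and on base composition were chosen only after the result was seen, and the score limit of 10000 and the start of the chromosome 4 segment were set after the scores were seen. Each reading takes the score to follow read depth, which no source used here states. Values are pooled over the lines, so no biological explanation by group was tested.

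Regions with a score of 10000 or more numbered 245, and 40.8% of them lay in 5 windows of 1 Mb, on chromosomes 8, 4, 5 and 11; 1 region outside these windows lay on a ribosomal RNA repeat, Rn18s-rs5 (44701). An amplified chromosome segment is argued against as the whole cause: these scores are at least 21.6 times the median, whereas other regions within 200000 bp had a median only 1.28 times that of all regions (bootstrap interval over windows of 1 Mb 1.16 to 1.43, an interval added after the ratio was seen), under the 1.5 that it would need. The ratio was not under the 1.2 set beforehand for no amplification, so amplification of part of these regions, or of pieces much shorter than 200000 bp, stays open. Reads from repeated sequence placed together at a few loci are a candidate explanation. Of these regions 67.3% had another such region within 50000 bp, against at most 6.53% in 1000 random draws from the whole list. Amplified short pieces could also place such regions close together, so this share does not tell the explanations apart. No repeat annotation was used here, so the repeat explanation stays a hypothesis.

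Scores were low over most of chromosome 4 from 120000001. The exception was 145000001 to 150000000, with a median of 667 among regions of 400 to 800 bp, against 640 on the rest of the autosomes. The zinc finger gene cluster with high scores at gene ends lay within that stretch. Lower depth near gene ends is argued against as the whole cause. The ratio to other autosomes was 0.755 (bootstrap interval 0.732 to 0.793) among regions over 10000 bp from any protein-coding gene end. Those regions can lie inside gene bodies, and gene density was not matched. The segments of distal chromosome 4 held a median of 72.5 protein-coding genes, against 31 over all segments. Lower depth in gene-dense sequence therefore stays open. Fewer copies of the segment in some of the lines may contribute: after a regression on gene number, its 8 segments had a mean residual of -0.33 (log2), with 0.0% of 359 autosomal runs lower, but a segment picked for low scores is low by choice, so this decides nothing. Base composition of gene-dense sequence also stays open, because no genome sequence was used: 1 of 131 other segments with at least 50 genes was as low, at 15000001 to 20000000 of chromosome 7.

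Cdkn2a, floxed in the mice behind all 8 lines, had a median score above 0.899% of comparable genes, but its regions were narrow (median 310 bp). Among all regions of matched width, the regions of Cdkn2a had a median percentile of 23.2, which is not a rank among genes. Loss of the whole gene in all 8 lines is argued against by the score of 623 inside it, above the median of all regions, although that region is wide (1140 bp) and no region of the gene was above percentile 50.4 at matched width; loss in some of the lines stays open. Low depth over the whole neighbourhood was not seen in the raw scores: the other 37 regions within 200000 bp had a median of 512, at percentile 67.8 of protein-coding genes. That rank was not matched for width, so it does not settle the question. Loss of part of the gene in the lines may contribute but cannot be told apart from an ordinary gap: the 6718 bp of the gene without a region belong to a gap of 16610 bp, and 17.2% of gaps are at least that long. Exon positions were not used here, so the part that recombination would remove is not known.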
